A study of Oryza sativa with 4 samples.

How the data were processed

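Paleas of 4 rice genotypes were profiled by RNA sequencing. Per the labels' protocols, plants were grown in a paddy field, total RNA was extracted and messenger RNA was enriched before library preparation. The labels give the background as japonica for the wild type and rep1 samples, Nipponbare for the Osmads6 sample and AF36 for the Osmads32 sample, so genotype and background cannot be separated. No developmental stage, batch or date was given in the sources used here.

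The deposited table holds FPKM values (fragments per kilobase of transcript, scaled to sequencing depth), made by the authors, for 55986 genes in 8 columns. Gene IDs are locus IDs of the LOC_Os series. The submitters' processing notes name the genome build IRGSP 1.0; the aligner, the counting tool and the annotation version are not given in the sources used here. The table has 2 columns per genotype where GEO lists 1 sample per genotype. They were treated as 2 runs of 1 sample, their mean is the sample's value, and n = 1. The runs of a genotype differed by more than counting noise: the median chi-square over its counting expectation was 32.4 for wild type, 7.10 for Osmads6, 9.58 for Osmads32 and 9.92 for rep1. Between the wild type runs 477 of 20675 genes differed by at least 2-fold, against 77, 128 and 168 in the same order. Whether the runs came from separate plants is not stated.

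Depth was worked out from the FPKM values. A gene's value in a run is a whole multiple of what 1 read is worth, and whole reads were found within a tolerance of 0.02 reads for 44686 genes, 99.9% of the genes above 0. They are fixed up to a factor common to the 8 runs of a gene. A further 27 abundant genes gave no whole reads and held 6.68% to 9.20% of the FPKM of a run, and 11273 genes were at 0 in all 8 runs. Recovered totals ran from 36215500 to 53262671 reads per run. They were used for depth, for the spread between runs and for the floor of 3 reads behind values of 0; this floor covers counting error only, as does the 1 interval given for a ratio (exact Clopper-Pearson on the reads of both runs).

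The measure computed was log2((mutant FPKM + 1)/(wild type FPKM + 1)) on the means of 2 runs, for the 20675 genes with a mean of at least 1 FPKM over the 4 genotypes. The pseudocount of 1 understates differences of low genes. "Higher" and "lower" mean at least 2-fold on this scale when genes are counted. Folds given for single genes are ratios of mean FPKM without the pseudocount. With 1 sample per genotype no test was made and no p-value is given. The median of a gene list was placed among 10000 random lists of the same size, matched on mean expression in 20 bins, and the range of the middle 95% is given as a description of these libraries. Overlap between mutants was set beside independent lists, 100 shuffles of the 4 values of each gene, and 100 simulations of unchanged mutants against the shared wild type sample. Paralogs of the MADS-box, light-harvesting, heat shock and cellulose synthase families can share reads, and their values are uncertain to that extent.

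The table does not pair locus IDs with gene names. Symbols were paired with locus IDs from published rice nomenclature as it was known, in 13 lists written before the data were examined. Each pair was checked against symbols and synonyms in the RefSeq gene table of assembly ASM3414082v1, which holds no LOC_Os IDs: the symbol had to lie on the same chromosome and in the same order as at least 90% of the other pairs there. Of 173 pairs, 136 passed, 0 were out of order, the symbol of 32 was absent from the table and that of 5 was found on another chromosome only. This check can miss a wrong pair of nearby genes. Genes named singly passed it, except OsMADS32 and REP1, which did not have a matching RefSeq symbol and were kept because they are the targeted genes. List medians use all 121 pairs of the first lists (84 checked), of which 1 has no row in the table. A further 26 lists were to be built from gene descriptions and were not run because no descriptions were given. After values of the first lists had been seen, 90 more pairs were tried for 6 added lists, and the 52 that passed the check were kept. Their themes were therefore chosen with the data in view, and the heat shock list was chosen after the values of its own members were seen, so it is not independent evidence of its direction.

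Genes to be named were chosen by a rule fixed beforehand: the targeted genes, the floral MADS-box and palea lists, the highest and lowest 2 members per list with a mean of at least 5 FPKM, the genes with the largest ratios whose runs do not overlap, and for the overlap the 8 genes each way with the largest smallest ratio. As the table gives no names, at most 2 locus IDs each way are printed, and list members were named only from checked pairs. Named outside the rule, after their values were seen, were SPL13 in Osmads6, COMT1 in rep1, GLK1 in the overlap, and RAFTIN1, EAT1, TDR, TIP2, CYCB1;1, CDKB2;1, HSP17.9A, HSP101, HSFA2A and HSP17.7 in the closing section.

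Alternatives fixed beforehand were pseudocounts of 0.1 and 5, no filter and a filter of 5 FPKM, division of each library by its median ratio, scaling to the library sum, a 4-fold threshold, genes whose runs do not overlap, and each run left out in turn. Added after the data were seen were checked pairs only, counts relative to the median ratio of all genes, the added lists, lists in the comparison of Osmads6 with Osmads32, further scalings of single genes, the exchange of the columns labelled wild type and Osmads6, DNA replication and mitosis genes of Osmads6 with no filter, and the simulation of unchanged mutants. The procedure was tested on simulated data. Whole reads were recovered for 100% of 4724 simulated genes. In a simulated comparison of a mutant with wild type over 20648 genes, 50 genes were changed at each of 4 sizes: 80% of those at a log2 change of 1.5, 62% at -1.5, 100% at 2 and 82% at -2 passed 2-fold, and 0.0098% of unchanged genes did. The simulation gave every gene the same spread between runs, set from the typical gap of the wild type runs. It leaves out genes of larger spread, and 477 of 20675 genes differed by at least 2-fold between those runs. It may also leave out differences between plants, as whether the runs came from separate plants is not stated. For these reasons 0.0098% is no rate of false calls for these libraries. Of 200 random unchanged lists, 95% lay inside the range. These lists were drawn from the same simulated genes as the random lists, so this checks the calculation only. Members of the real lists can vary together, which these lists leave out. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.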

Results

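Gene expression was measured by bulk RNA sequencing of rice paleas. The palea is the inner of the pair of bracts that enclose the rice flower, opposite the lemma. The 4 samples were labelled wild type, Osmads6 (a line with an inserted Tos17 retrotransposon), Osmads32 (a line with a T-DNA insertion) and rep1 (a deletion line). OsMADS6 and OsMADS32 encode MADS-box transcription factors of floral patterning, and REP1 encodes a TCP transcription factor of palea development. GEO lists 1 sample per genotype, and the 2 columns of each were treated as runs of that sample. On this choice n = 1 per genotype, and no test between genotypes was made. Whether the columns came from separate plants is not stated. The 2 values after a gene are those of the 2 runs and describe their spread only. Recovered depth was 53262671 and 48986393 reads in the wild type runs, 36215500 and 39867408 in the Osmads6 runs, 43196918 and 42597728 in the Osmads32 runs and 38535993 and 36637312 in the rep1 runs. None of the differences below has a replicate check.

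The targeted genes were examined first. OsMADS6 (LOC_Os02g45770) was lowest in the library labelled wild type, at 13.5 FPKM (12.5 and 14.4), against 127 FPKM (124 and 130) in the library labelled Osmads6. It reached 262 FPKM in the library labelled Osmads32 and 842 FPKM in the library labelled rep1, which were 19.5-fold and 62.6-fold above wild type. OsMADS32 (LOC_Os01g52680) stood at 7.19 FPKM in the library labelled wild type (6.63 and 7.75) and at 8.32 FPKM in its own labelled mutant (8.69 and 7.95). It was 2.08-fold higher in the library labelled Osmads6, at 14.9 FPKM, and 2.59-fold lower in the library labelled rep1, at 2.78 FPKM. REP1 (LOC_Os09g24480) was near the detection limit everywhere, with 4 and 11 reads in the wild type runs and 2 and 0 reads in the rep1 runs, so its level does not check the rep1 label. An insertion or a small deletion need not lower a transcript, and where the reads of these genes fell relative to the lesions is not known. The level of OsMADS6 ran against the wild type and Osmads6 labels, and OsMADS32 was not lower in its own mutant. Samples are therefore named as the library labelled with a genotype, and every direction below rests on those labels. With the columns labelled wild type and Osmads6 exchanged, every ratio for Osmads6 against wild type turns by construction. The 8 of 19 gene list medians outside the random range there crossed to its other side, and the others turned inside it. The number that moved into, out of or across the range was 10 of 19 for Osmads32 against wild type. It was also 10 of 19 for rep1 against wild type and for Osmads6 against Osmads32.

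**Figure D1:**
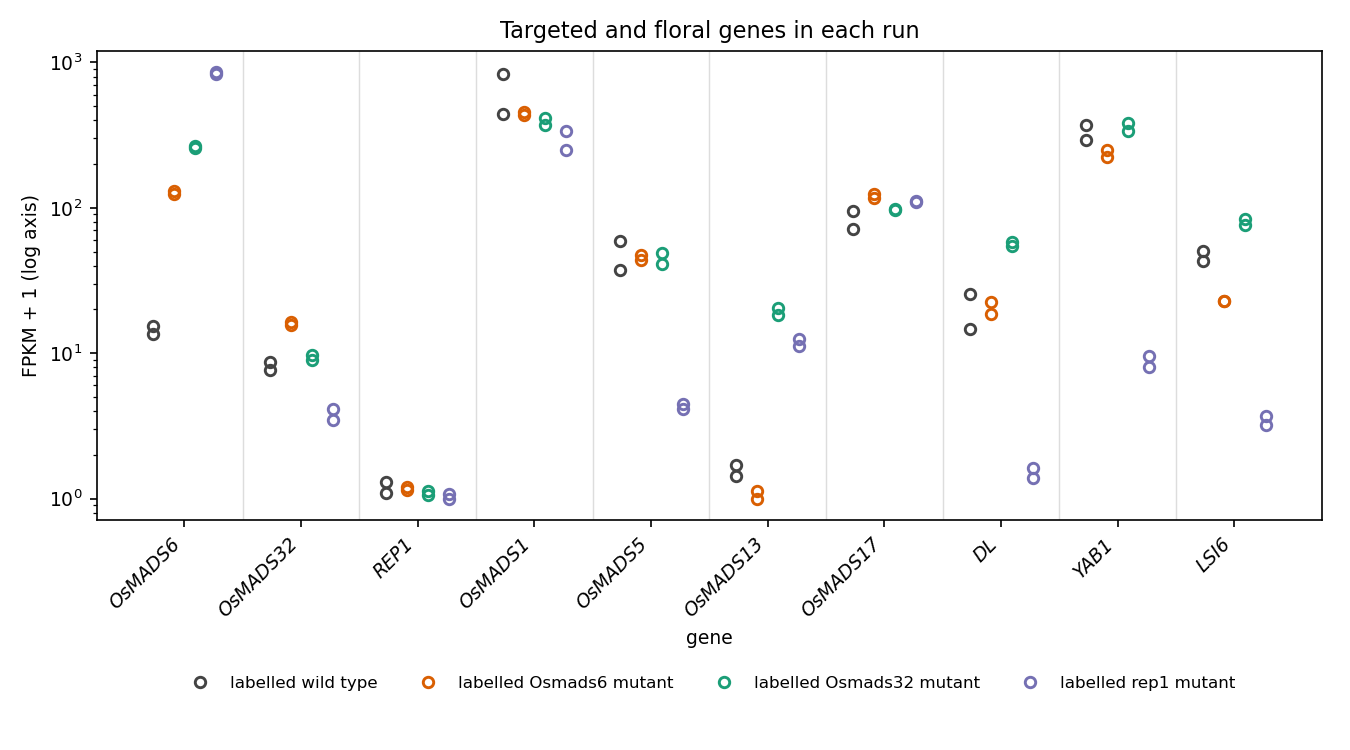
FPKM + 1 of 10 genes on a log axis, with 1 circle per run and colours for the 4 labelled genotypes. OsMADS6 is lowest in both wild type runs (12.5 and 14.4 FPKM) and highest in both rep1 runs, while YAB1, DL, OsMADS5 and LSI6 are lowest in both rep1 runs.

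What differed between paleas labelled Osmads6 and wild type was asked next. Nuclear genes of light harvesting and the photosystems were lower together in the library labelled Osmads6: 20 of 21 measured members were at least 2-fold lower and the median log2 ratio was -1.69. The 21 include a Rubisco activase gene and a Rubisco small subunit gene. Most symbols of this list were absent from the RefSeq table, so their locus IDs were not checked. The light-harvesting gene CAB1R (LOC_Os09g17740) stood at 98.7 FPKM against 738 FPKM, and CAB2R (LOC_Os01g41710) was 6.83-fold lower. Cellulose synthases of the secondary wall were lower in 3 of 3 members (median -1.88), with CESA4 (LOC_Os01g54620) at 119 against 440 FPKM and CESA9 (LOC_Os09g25490) at 38.1 against 152 FPKM. RTS (LOC_Os01g70440), a tapetum gene, gave 0 reads in both Osmads6 runs against 116 FPKM in wild type, which is at least 905.5-fold lower at a floor of 3 reads per run. OsC6 (LOC_Os11g37280), a lipid transfer protein of the anther, was 158-fold lower at 0.551 FPKM.

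Genes of grain and hull size were higher in the library labelled Osmads6 in 6 of 8 measured members (median 1.30). SPL16 (LOC_Os08g41940), which promotes grain width, stood at 35.5 FPKM (34.4 and 36.6) against 6.93 FPKM (7.21 and 6.64), and SPL13 (LOC_Os07g32170) was 2.11-fold higher. Of 4 YABBY genes, which encode transcription factors of lateral organs, 3 were at least 2-fold higher (median 1.55). YAB3 (LOC_Os10g36420) was 3.74-fold higher and YAB1 (LOC_Os07g06620) stood at 235 against 330 FPKM. With members of at least 5 FPKM only, the YABBY median was 0.64 and lay inside the range of random lists. The floral MADS-box list had 1 member higher (OsMADS6) and 2 lower among 19, and its median of -0.34 lay inside the random range. It lay below the range with a pseudocount of 0.1 (-0.44) and with checked members only (-0.38). The lower members were OsMADS3 (LOC_Os01g10504), a stamen and carpel identity gene, 3.96-fold lower at 1.22 FPKM, and OsMADS8 (LOC_Os09g32948), 2.20-fold lower at 12.9 FPKM. DROOPING LEAF (DL, LOC_Os03g11600), a carpel and leaf midrib gene, was level at 19.6 against 19.1 FPKM.

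Medians of the other lists fixed beforehand lay inside the range of random lists for Osmads6 against wild type: palea and floral organ identity (0.04), meristem KNOX (-0.22), anther and tapetum (-0.15, with 5 of 13 members lower and 1 higher, a median that a bound for RTS does not move, and -1.5, below the range, with members of at least 5 FPKM), DNA replication and mitosis (0.31), primary wall cellulose synthase (-0.30), silicon transport (-1.03, from LSI6 alone), jasmonate (0.13) and housekeeping (0.15). Among lists chosen after the first values were seen, secondary wall assembly and lignin was lower in 3 of 5 members (median -1.30), and its caffeic acid O-methyltransferase COMT1 (LOC_Os08g06100) stood at 399 against 1129 FPKM. One member ran the other way: 4CL5 (LOC_Os08g34790) was 3.28-fold higher. Chlorophyll synthesis and GLK genes were lower in 4 of 8 members (median -1.24), with PORA (LOC_Os04g58200), a protochlorophyllide reductase, 9.01-fold lower. Epidermis and cuticle genes were higher in 2 of 4 members (median 1.09), with the homeobox gene ROC2 (LOC_Os04g53540) at 31.7 against 8.67 FPKM. The SPL and growth-regulating factor list (0.23) and the gibberellin list (0.24) lay inside the random range.

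Among 20675 genes, 1592 were at least 2-fold higher and 1544 at least 2-fold lower in the library labelled Osmads6, 15.2% in all. The values of the 2 genotypes did not overlap between runs in 1589 and 1541 of them. Outside the lists, LOC_Os01g37000 stood at 410 against 0.0748 FPKM, LOC_Os08g08960 at 316 against 0.104 FPKM, and LOC_Os01g41140 at 0.363 against 115 FPKM. The count depended on the threshold, with 292 higher and 271 lower at 4-fold.

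**Figure D2:**
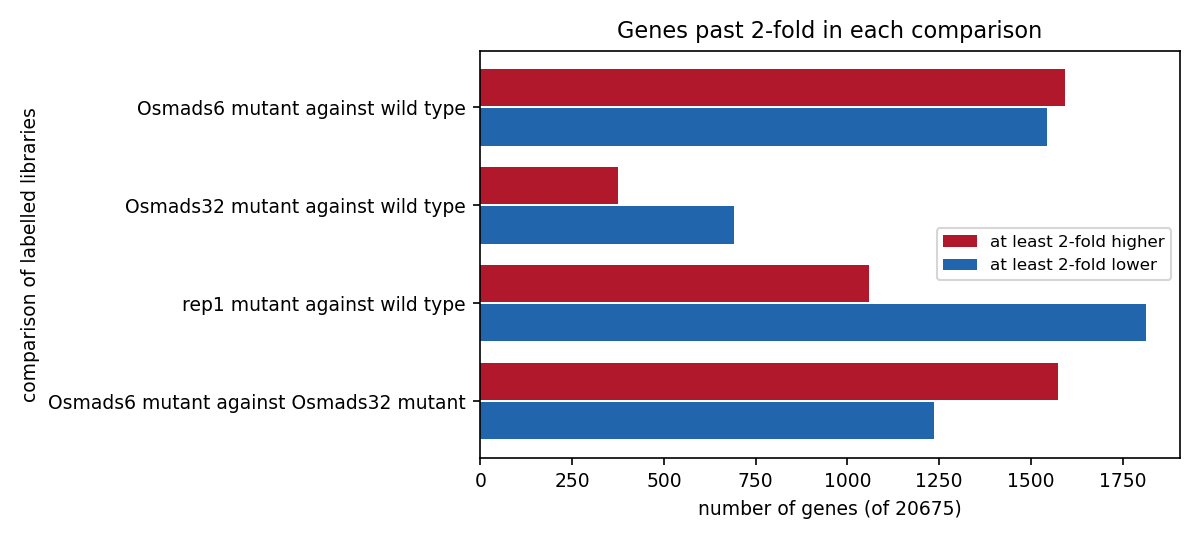
Number of genes at least 2-fold higher (red) or lower (blue) among 20675 genes in each comparison of labelled libraries; bars start at 0. The library labelled Osmads32 differs least from wild type, with 375 genes higher and 690 lower.

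The library labelled Osmads32 was the closest to wild type of the 3 labelled mutants. OsMADS13 (LOC_Os12g10540), an ovule identity gene, was 33.2-fold higher at 18.5 FPKM against 0.557 FPKM. DL was 2.92-fold higher at 55.6 FPKM (53.7 and 57.4) against 19.1 FPKM (24.5 and 13.6), and the carpel gene OsMADS58 (LOC_Os05g11414) stood at 6.06 against 0.345 FPKM. Floral MADS-box genes were at least 2-fold higher in 4 of 19 members and lower in 1 (median 0.24), the lower one being OsMADS34 (LOC_Os03g54170), 4.66-fold lower at 1.87 FPKM. OsMADS7 (LOC_Os08g41950), a gene active in the inner floral organs, was 3.18-fold higher.

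Jasmonate genes had a median of 0.73 for Osmads32 against wild type, with 2 of 6 members at least 2-fold higher: the JAZ repressor genes TIFY11B (LOC_Os03g08330) at 137 against 39.7 FPKM and TIFY11A (LOC_Os03g08310) at 59.4 against 19.8 FPKM. The medians of palea and floral organ identity (0.85, with DL the only 1 of 5 members past 2-fold), meristem KNOX (0.77) and grain and hull size genes (0.52) also lay above the range of random lists, with no member past 2-fold in the last 2 lists. The KNOX median of members of at least 5 FPKM, 0.42, lay inside the range. Light harvesting and photosystem genes were lower, with 6 of 21 members past 2-fold and a median of -0.72, and CAB1R was 3.02-fold lower at 245 FPKM. This direction rests on the labels: with the columns labelled wild type and Osmads6 exchanged, 10 of 21 members were higher and the median was 0.97, above the range. The grain and hull size median was then -0.75, below the range, with 3 of 8 members lower. The jasmonate median was then 0.47, inside the range. As labelled, medians inside the range were those of anther and tapetum (-0.24), DNA replication and mitosis (0.11), primary wall (0.05) and secondary wall cellulose synthase (0.44), silicon transport (0.76), YABBY (0.04, with a mean of -0.16) and housekeeping genes (-0.08). The anther and tapetum median lay below the range with members of at least 5 FPKM (-0.33) and with a pseudocount of 0.1 (-0.34).

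Of the lists chosen later, chlorophyll synthesis and GLK genes were lower in 4 of 8 members for Osmads32 against wild type (median -0.73). GLK1 (LOC_Os06g24070), a transcription factor of chloroplast development, was 19.9-fold lower at 1.44 against 28.7 FPKM. SPL and growth-regulating factors had a median of 0.44, with GRF3 (LOC_Os04g51190) 3.17-fold higher. Secondary wall assembly and lignin genes had a median of 0.38 against an upper end of the random range of 0.37, with no member past 2-fold, and lay inside the range after median-ratio scaling (0.42) and with members of at least 5 FPKM (0.38). The gibberellin list (-0.17) and the epidermis and cuticle list (0.07, with a mean of -0.02) lay inside it. These directions rest on the labels. With the columns labelled wild type and Osmads6 exchanged, the chlorophyll synthesis and GLK median was 0.51, above the range, with 2 of 8 members higher. That of SPL and growth-regulating factors was 0.35, inside the range, and that of epidermis and cuticle genes was -1.295, below it.

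At least 2-fold differences numbered 375 higher and 690 lower among 20675 genes, and runs did not overlap in 371 and 684 of them. Without wild type run 1, 682 genes were higher and 797 lower, so the number of higher genes rested in part on that run. The pair with the largest log2 ratios upward were OsMADS6 and OsMADS13, and those downward were LOC_Os04g28420, at 11 against 316 FPKM, and the heat shock gene HSP17.4 (LOC_Os03g16020), at 6.0 against 174 FPKM.

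In the library labelled rep1, YAB1, DL, OsMADS5 and LSI6 were far below wild type. YAB1 was 42.1-fold lower at 7.82 FPKM (8.57 and 7.07) against 330 FPKM (290 and 369). DL was 38.2-fold lower at 0.499 FPKM, OsMADS5 (LOC_Os06g06750), a SEPALLATA-like gene, was 14.4-fold lower at 3.28 FPKM, and the silicon transporter gene LSI6 (LOC_Os06g12310) was 18.7-fold lower at 2.45 FPKM. All 3 secondary wall cellulose synthases were higher (median 1.38), with CESA4 at 1145 against 440 FPKM and CESA9 3.17-fold higher. KNOX genes of meristem identity were higher in 3 of 3 members (median 1.75), with OSH43 (LOC_Os03g56110) at 73.1 against 21.1 FPKM and OSH71 (LOC_Os05g03884) at 13.1 against 2.29 FPKM.

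Floral MADS-box genes went both ways for rep1 against wild type, with 7 of 19 higher, 5 lower and a median of 0.41. Besides OsMADS6, OsMADS13 was 19.5-fold higher at 10.8 FPKM, OsMADS7 3.08-fold higher and OsMADS3 3.06-fold higher. OsMADS15 (LOC_Os07g01820), an APETALA1-like gene, was 2.89-fold lower and OsMADS1 (LOC_Os03g11614), a SEPALLATA-like gene of lemma and palea identity, stood at 293 FPKM (249 and 337) against 635 FPKM (440 and 830). YABBY genes were lower in 3 of 4 members (median -1.60). Palea and floral organ identity genes had a median of 0.71 and a mean of -0.21, with 2 of 5 members higher and DL lower. Over the members whose locus ID was checked, the median was -1.36, and with members of at least 5 FPKM it was 0.20 and inside the range, so the list gives no direction. Medians inside the random range were those of anther and tapetum (-0.14), light harvesting and photosystem genes (-0.23, with no member of 21 past 2-fold), DNA replication and mitosis (-0.45), primary wall cellulose synthase (-1.15), jasmonate (-0.49), grain and hull size (-0.46) and housekeeping genes (-0.49). The DNA replication and mitosis median lay below the range with a pseudocount of 0.1 (-0.90) and with members of at least 5 FPKM (-3.25). With the columns labelled wild type and Osmads6 exchanged, 18 of 21 light harvesting and photosystem genes were higher in rep1, with a median of 1.46, above the range. Within these lists, the cyclin gene CYCB2;1 (LOC_Os04g47580) was 34.1-fold lower, the cyclin-dependent kinase gene CDKB1;1 (LOC_Os01g67160) was 12.3-fold lower and SPL16 was 6.60-fold lower. The actin gene ACT1 (LOC_Os03g50885), counted as housekeeping, was 2.58-fold lower at 218 against 563 FPKM.

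Of the lists chosen later, secondary wall assembly and lignin was higher in 4 of 5 members for rep1 against wild type (median 1.47). COMT1 stood at 2931 against 1129 FPKM and 4CL3 (LOC_Os02g08100), a 4-coumarate ligase gene, was 4.72-fold higher. SPL and growth-regulating factors had a median of 0.41 with no member of 7 past 2-fold, and with a pseudocount of 0.1 this median lay inside the range. Chlorophyll synthesis and GLK (-0.25), gibberellin (-0.22) and epidermis and cuticle genes (-0.51) lay inside the random range.

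At least 2-fold differences numbered 1060 higher and 1815 lower among 20675 genes for rep1 against wild type, with runs apart in 1055 and 1805. The median log2 ratio of all genes was -0.15. Relative to it, 1362 genes were higher and 1386 lower, so the share of higher genes among those past 2-fold was 49.6% in place of 36.9%. The ranges of random lists carry the same shift. Outside the lists, LOC_Os07g44250 stood at 196 against 1.82 FPKM, LOC_Os10g05930 at 5.57 against 1112 FPKM and LOC_Os10g05820 at 1.14 against 223 FPKM.

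**Figure D3:**
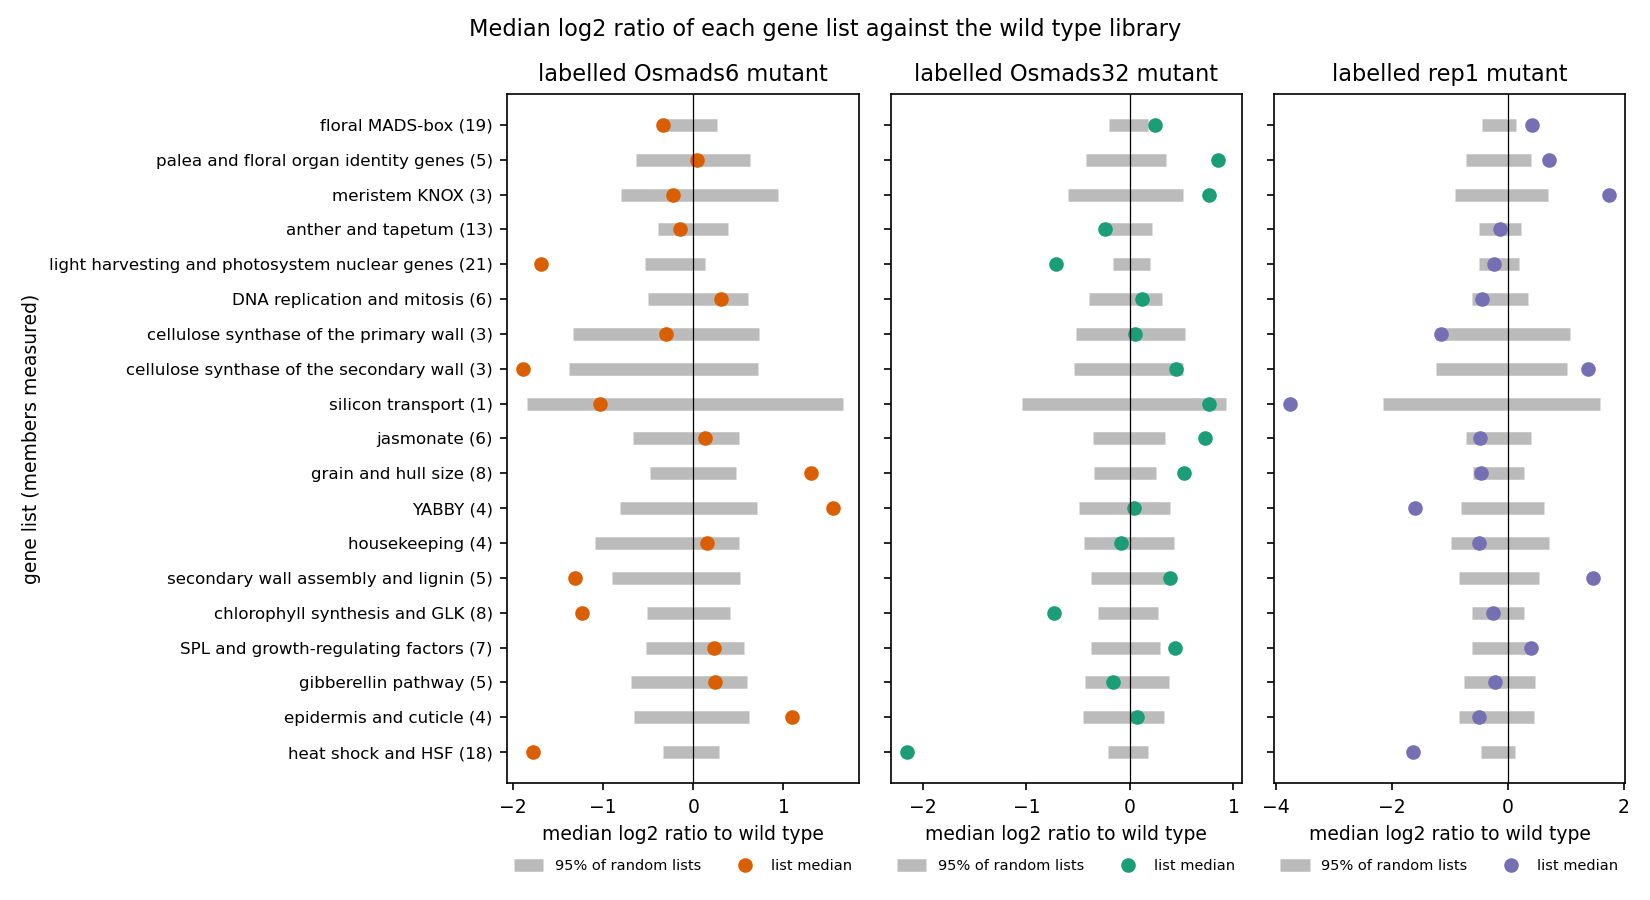
Median log2 ratio to the library labelled wild type (points) for 19 gene lists in each labelled mutant, with the range of 95% of random lists matched on expression (grey bars); the number of members measured is in parentheses and the x axes differ between panels. Secondary wall cellulose synthases lie at -1.88 in the library labelled Osmads6 and at 1.38 in the library labelled rep1, and YABBY genes at 1.55 and -1.60.

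The series title pairs OsMADS6 with OsMADS32, and their labelled libraries were compared directly, a ratio that does not use the library labelled wild type. It still rests on the labels. With the columns labelled wild type and Osmads6 exchanged, 10 of 19 list medians moved into, out of or across the random range. Light harvesting and photosystem, grain and hull size and chlorophyll synthesis and GLK medians turned to the opposite side. Those of anther and tapetum, YABBY and epidermis and cuticle genes turned and moved inside. Those of secondary wall cellulose synthase and silicon transport moved inside. OsMADS13 was lower in the library labelled Osmads6, at 0.0615 FPKM from 3 and 0 reads against 18.5 FPKM from 499 and 551 reads. The ratio, 301-fold, has a 95% counting interval from 103-fold to 1461-fold. OsMADS3 was 6.0-fold lower, OsMADS7 4.33-fold lower and DL 2.83-fold lower. Of 19 floral MADS-box genes, 9 were at least 2-fold lower and 1, OsMADS34, higher (median -0.58). Secondary wall cellulose synthases were lower in 3 of 3 members (median -2.33), and light harvesting and photosystem genes in 10 of 21 (median -0.97). Palea and floral organ identity (-1.08), meristem KNOX (-1.09), anther and tapetum (-0.69) and silicon transport (-1.79) had medians below the random range, and grain and hull size (0.75) and YABBY genes (1.45) above it. With members of at least 5 FPKM the KNOX (-0.82) and YABBY medians (0.44) lay inside the range, as did those of anther and tapetum (-0.0038), light harvesting and photosystem (-1.14) and grain and hull size genes (0.58) with checked members only, and that of silicon transport (-1.83) with a pseudocount of 0.1. DNA replication and mitosis (0.57), primary wall cellulose synthase (-0.28), jasmonate (-0.47) and housekeeping genes (0.09) lay inside it. Of the lists chosen later, secondary wall assembly and lignin (-1.62) and chlorophyll synthesis and GLK (-0.51) were below the range and epidermis and cuticle (1.29) above it, while SPL and growth-regulating factors (-0.35) and gibberellin genes (0.57) lay inside. In all, 1573 genes were at least 2-fold higher and 1236 lower.

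**Figure D4:**
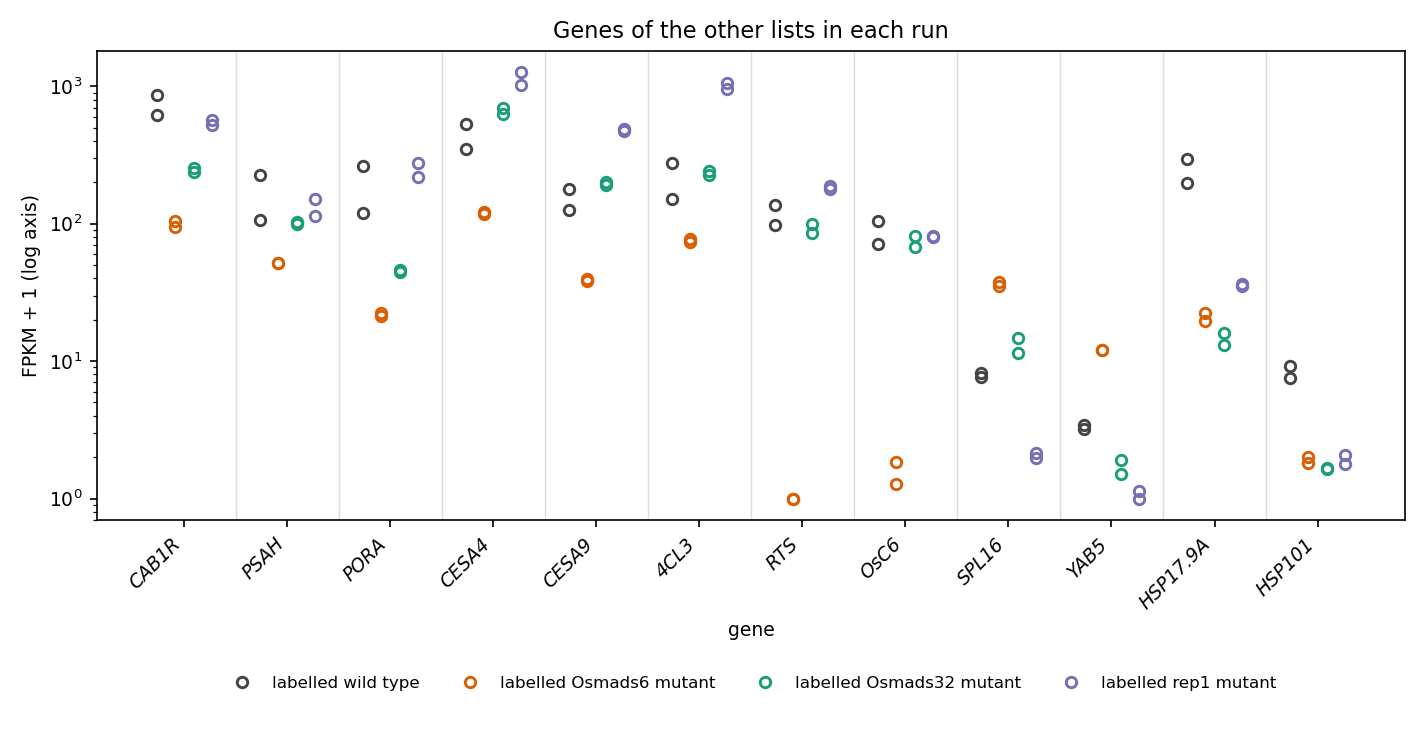
FPKM + 1 of 12 genes from the other lists on a log axis, with 1 circle per run and colours for the 4 labelled genotypes. RTS is at 0 FPKM in both Osmads6 runs, CESA4, CESA9 and 4CL3 are lowest in the Osmads6 runs and highest in the rep1 runs, and HSP17.9A and HSP101 are highest in the wild type runs.

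Whether the labelled mutants shared differences was examined last. OsMADS6 ranked first among the 24 genes higher in all 3 labelled mutants, and the small heat shock protein genes HSP17.4 and HSP18.0 (LOC_Os01g08860) ranked the third and the fourth among the 100 genes lower in all 3. HSP18.0 stood at 264 FPKM in the library labelled wild type and at 18.3, 20.5 and 30.2 FPKM in those labelled Osmads6, Osmads32 and rep1. GLK1 was also lower in all 3. The libraries labelled Osmads6 and Osmads32 had 126 genes higher in both and 359 lower in both, and 53 in opposite directions. Those labelled Osmads6 and rep1 had 100 higher in both, 262 lower in both and 588 opposite. Those labelled Osmads32 and rep1 had 88, 223 and 84.

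All 3 comparisons used the same wild type library, which creates overlap by itself. Independent lists of these sizes would share 28.9 genes higher and 51.5 lower for Osmads6 with Osmads32, 81.6 and 136 for Osmads6 with rep1, and 19.2 and 60.6 for Osmads32 with rep1, and 1.48 higher and 4.52 lower in all 3. Unchanged mutants simulated from the spread between runs shared 6.86 higher and 7.20 lower for Osmads6 with Osmads32, and 3.85 and 3.97 in all 3. Whether the runs came from separate plants is not stated. This spread may therefore leave out differences between plants, and these may be low estimates. When the 4 values of each gene were shuffled over the genotypes 100 times, a mean of 435 genes were higher and 427 lower in all 3. Shuffling keeps the differences between genotypes and can put a value particular to 1 mutant in the place of the wild type. These counts therefore hold such differences and are no estimate of what a shared control alone creates. The covariance of log2 ratios across genes was 0.15 for Osmads6 with Osmads32, -0.05 for Osmads6 with rep1 and 0.08 for Osmads32 with rep1, against 0.05 in each simulated pair. Without wild type run 1, 86 genes were higher in all 3 and 288 in both Osmads6 and Osmads32. With 1 wild type sample the control could not be split, so part of any overlap may come from it. The overlap also rests on the labels: with the columns labelled wild type and Osmads6 exchanged, 595 genes were higher and 919 lower in all 3. OsMADS6 was then lower in Osmads6 (log2 ratio -3.15) and higher in Osmads32 (1.04) and rep1 (2.72).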

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

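The tests of explanations in this part, the exchange of columns, the DNA replication and mitosis median with no filter and the alternatives for secondary wall assembly and lignin were chosen after the results they bear on were seen. The differences between labelled mutants given here were not tested, since each genotype was treated as 1 sample.

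Gene lists that lay outside the random range in opposite directions in 2 labelled mutants, with the same sign in every pair of runs, were singled out. The median of secondary wall cellulose synthases was -1.88 for Osmads6 and 1.38 for rep1, a difference of -3.26 (Osmads6 minus rep1). The YABBY medians were 1.55 and -1.60, a difference of 3.15. Secondary wall assembly and lignin genes had medians of -1.30 for Osmads6, 0.38 for Osmads32 and 1.47 for rep1, differences of -1.69 (Osmads6 minus Osmads32) and -2.78 (Osmads6 minus rep1). The YABBY median for Osmads6 lay inside the range with members of at least 5 FPKM (0.64). That of secondary wall assembly and lignin for Osmads32 lay inside it after median-ratio scaling (0.42) and with members of at least 5 FPKM (0.38). The opposite directions rest on the labels. With the columns labelled wild type and Osmads6 exchanged, the medians for Osmads6 and rep1 were 1.88 and 3.26 for secondary wall cellulose synthases and -1.55 and -3.40 for YABBY genes. Those of secondary wall assembly and lignin were 1.305 for Osmads6, 1.62 for Osmads32 and 2.825 for rep1.

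The first pattern weighed is OsMADS6, lowest in the library labelled wild type. Library scaling is argued against by a smallest log2 ratio of 3.11 over the 3 labelled mutants and 4 settings. Reads shared with the paralog OsMADS17 are argued against by their summed FPKM, whose smallest log2 ratio to wild type was 1.37. An exchange of the columns labelled wild type and Osmads6 cannot be told apart from a difference of genotype or background: OsMADS6 was 9.45-fold higher in the library labelled Osmads6, and no other value examined here identifies either genotype. The genotype and the background of the lines stay open as untested explanations.

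The second pattern is the library labelled Osmads6, in which RTS, OsC6, light harvesting and secondary wall cellulose synthase genes were low. FPKM values are scaled to depth, so lower depth could remove these genes only by leaving too few reads to count. At the wild type level each of these 26 genes would have given at least 1086 reads in an Osmads6 run. Genes this abundant could not have failed this check, so it describes the depth and is no test of an explanation. Less anther material at an equal stage, as the whole source of low RTS and OsC6, was weighed by 11 other measured anther and tapetum genes. RTS and OsC6 were named as the lowest members of this list. That the others lay above them was fixed by that choice and is no evidence. That the others did not fall together was not fixed, and argues against this explanation for these 11 genes. Their median log2 ratio without a pseudocount was -0.068 (SD 1.64), from -3.51 to 2.05, against -7.305 for OsC6. Of the 11, 6 were lower by any amount. They went both ways: RAFTIN1 (LOC_Os08g38810) was 11.4-fold lower and EAT1 (LOC_Os04g51070) 2.65-fold lower, while TDR (LOC_Os02g02820) was 4.14-fold and TIP2 (LOC_Os01g18870) 3.31-fold higher. With members of at least 5 FPKM the median of the whole list, -1.5, lay below the range, and less anther material as a part of the source stays open. Younger organs in this sample may account for the pattern and cannot be told apart from an effect of genotype or background. The labels give no stage, and the median of 6 DNA replication and mitosis genes, 0.31, lay inside the random range. Within that list CYCB1;1 (LOC_Os01g59120) was 6.28-fold higher and CDKB2;1 (LOC_Os08g40170) 5.40-fold higher. With the pseudocount of 1 these were the 2 of 12 listed members past 2-fold, and 10 of 12 were higher by any amount. The 6 members under 1 FPKM were all higher, by 1.92-fold to 16.8-fold without the pseudocount. With the 6 members under 1 FPKM included, the median of 12 was 0.49, above a random range that ended at 0.42. CYCB2;1 and CDKB1;1 lay below wild type by less than 2-fold, and a stage cannot be separated from the genotype or the background with 1 sample. The genotype and the background stay open and were not tested.

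The third pattern is the low YAB1, DL, OsMADS5 and LSI6 in the library labelled rep1. Library scaling is argued against by the log2 ratio nearest to 0 over the 4 genes and 4 settings, -3.38. A single deletion that holds these genes is argued against by their places on 3 chromosomes. Less carpel material, which might lower DL, could not be weighed by OsMADS13, whose log2 ratio was 2.72 in the lowest pair of runs. OsMADS13 is 1 gene, at 0.557 FPKM in wild type, and was also 33.2-fold higher in the library labelled Osmads32. Its level need not follow the amount of carpel. Less carpel material, a different share of palea regions or of lemma tissue, the stage, the background and the genotype stay open and were not tested.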

How the results depend on the processing

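No paired analysis was made because each genotype was treated as 1 sample, and no result came from a test. Chosen after the data were seen were checked pairs only, centring on the median of all genes, the exchange of columns, the added lists, all lists in Osmads6 against Osmads32, and a pseudocount of 0.1 on single genes; the other choices varied in this part were fixed before the data were examined. Counts of genes past a threshold were within 1.5 times those reported under median-ratio scaling, library-sum scaling, no filter and runs that do not overlap. Causes of the shifts below were not tested, except that a stricter threshold, filter or larger pseudocount admits fewer genes by construction. Depth limits REP1, OsMADS13 in Osmads6 and other genes of a few reads.

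For Osmads32 against wild type a pseudocount of 0.1 gave 687 genes higher and 1088 lower, with 89 higher in all 3 labelled mutants and 323 higher in both Osmads6 and Osmads32. A pseudocount of 5 gave 751 higher and 746 lower for Osmads6, 126 and 289 for Osmads32, 571 and 805 for rep1, 763 and 611 for Osmads6 against Osmads32, 6 and 45 in all 3, and 32 and 166 in both Osmads6 and Osmads32. With a mean of at least 5 FPKM, 939 were higher for Osmads6, 228 higher and 448 lower for Osmads32, 702 higher for rep1, 927 higher for Osmads6 against Osmads32, 15 higher and 63 lower in all 3, and 74 higher in both Osmads6 and Osmads32. At 4-fold the numbers were 292 and 271 for Osmads6, 35 and 116 for Osmads32, 220 and 394 for rep1, 358 and 184 for Osmads6 against Osmads32, 2 and 20 in all 3, and 5 and 62 in both Osmads6 and Osmads32. Leaving out each run in turn gave 362 to 682 genes higher for Osmads32 against wild type, 22 to 86 higher in all 3 and 116 to 288 higher in both Osmads6 and Osmads32; the highest of each was without wild type run 1. With the columns labelled wild type and Osmads6 exchanged, 1236 genes were higher and 1573 lower for Osmads32, 2219 and 3425 for rep1, and 690 and 375 for Osmads6 against Osmads32. Then 595 were higher and 919 lower in all 3, and 776 and 1036 in both Osmads6 and Osmads32. The log2 ratio of OsMADS6 was then -3.15 in Osmads6, 1.04 in Osmads32 and 2.72 in rep1.

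OsMADS6 in rep1 had a log2 ratio of 6.0 under median-ratio scaling, and REP1 had -0.64 in Osmads32 and -1.17 in rep1 with a pseudocount of 0.1. Of 76 list medians, 75 kept their side of the random range under median-ratio scaling, 71 with a pseudocount of 0.1, 67 with members of at least 5 FPKM and 71 with checked pairs only. With the exchange of columns, 38 of 76 stayed inside the range or on the same side outside it. This number includes the medians inside the range for Osmads6 against wild type, which changed sign there by construction. With a pseudocount of 0.1, floral MADS-box in Osmads6 (-0.44), anther and tapetum in Osmads32 (-0.34) and DNA replication and mitosis in rep1 (-0.90) moved outside, and SPL and growth-regulating factors in rep1 (0.41) and silicon transport in Osmads6 against Osmads32 (-1.83) moved inside. Under median-ratio scaling, secondary wall assembly and lignin in Osmads32 (0.42) moved inside. With members of at least 5 FPKM, anther and tapetum in Osmads6 (-1.5) and Osmads32 (-0.33) and DNA replication and mitosis in rep1 (-3.25) moved outside; YABBY in Osmads6 (0.64) and in Osmads6 against Osmads32 (0.44), meristem KNOX in Osmads32 (0.42) and in Osmads6 against Osmads32 (-0.82), secondary wall assembly and lignin in Osmads32 (0.38) and palea and floral organ identity in rep1 (0.20) moved inside. With checked pairs only, palea and floral organ identity in rep1 turned to -1.36, floral MADS-box in Osmads6 (-0.38) moved outside, and in Osmads6 against Osmads32 anther and tapetum (-0.0038), light harvesting and photosystem genes (-1.14) and grain and hull size (0.58) moved inside. With the exchange of columns the 8 medians outside the range for Osmads6 turned by construction: light harvesting and photosystem (1.69), secondary wall cellulose synthase (1.88), grain and hull size (-1.30), YABBY (-1.55), secondary wall assembly and lignin (1.305), chlorophyll synthesis and GLK (1.24), epidermis and cuticle (-1.09) and heat shock (1.77). For Osmads32, light harvesting and photosystem (0.97), grain and hull size (-0.75) and chlorophyll synthesis and GLK (0.51) turned to the opposite side of the range. Anther and tapetum (0.69), secondary wall cellulose synthase (2.33), silicon transport (1.79), YABBY (-1.45) and epidermis and cuticle (-1.295) moved outside, and jasmonate (0.47) and SPL and growth-regulating factors (0.35) inside. For rep1, light harvesting and photosystem (1.46), DNA replication and mitosis (-1.70), jasmonate (-1.355), grain and hull size (-1.72), chlorophyll synthesis and GLK (0.92) and epidermis and cuticle (-1.84) moved outside. Palea and floral organ identity (0.63), silicon transport (-2.73), SPL and growth-regulating factors (0.23) and heat shock (0.23) moved inside. For Osmads6 against Osmads32, anther and tapetum (0.24), YABBY (-0.037) and epidermis and cuticle (-0.072) turned and moved inside. Light harvesting and photosystem (0.72), grain and hull size (-0.52) and chlorophyll synthesis and GLK (0.73) turned to the opposite side. Secondary wall cellulose synthase (-0.44) and silicon transport (-0.76) moved inside, and jasmonate (-0.73) and SPL and growth-regulating factors (-0.44) outside.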

Other observations

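The choices in this part were made after the data were seen. Heat shock genes were highest in the library labelled wild type. Of 18 measured members, 12 were at least 2-fold lower in the library labelled Osmads6 (median -1.77), 11 in that labelled Osmads32 (median -2.16) and 14 in that labelled rep1 (median -1.64), all outside the random range, as was the median of Osmads6 against Osmads32 (0.51). With the columns labelled wild type and Osmads6 exchanged, the medians were 1.77 for Osmads6, -0.51 for Osmads32 and 0.23 for rep1, the last inside the range, so the shared lower level rests on the labels. Both wild type runs lay above the 6 other runs for 12 members. HSP17.9A (LOC_Os03g15960), a small heat shock protein, stood at 247 FPKM (296 and 198) in the library labelled wild type and at 20, 13.6 and 35.0 FPKM in those labelled Osmads6, Osmads32 and rep1. The disaggregase gene HSP101 (LOC_Os05g44340) stood at 7.37, 0.910, 0.647 and 0.935 FPKM in the same order, and the heat shock factor gene HSFA2A (LOC_Os03g53340) at 8.49, 0.195, 0.234 and 0.562 FPKM. Not all members followed: HSP17.7 (LOC_Os03g16040) stood at 47.9, 44.4, 31.2 and 49.8 FPKM. As members were chosen after their values were seen, the count is a description and not independent evidence.

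The libraries labelled Osmads6 and rep1 were the farthest apart of the 6 pairs. Between them 5644 of 20675 genes differed by at least 2-fold, 2219 higher and 3425 lower in rep1, and the correlation of expression across genes ran from 0.778 to 0.779 between runs, where genes are not independent replicates. Wild type and Osmads32 were the closest, at 0.944 to 0.955. In both Osmads6 runs 10 genes were under 0.1 FPKM that exceeded 3 FPKM in all 6 other runs, against 3 in rep1 and 0 in wild type and Osmads32.

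The 10 expressed loci nearest to REP1 by locus number, 5 on each side, had log2 ratios of rep1 to the mean of the other genotypes from -0.36 to 0.84, so none was past 2-fold and any deletion there left these loci expressed. Elsewhere, 6 neighbouring expressed loci on chromosome 10, from LOC_Os10g05820 to LOC_Os10g05930, were each at least 8-fold lower in the library labelled rep1 than in any other genotype. The longest such stretch was 3 loci in Osmads6 and 1 in wild type and Osmads32. Loci this low numbered 208 in rep1, 89 in Osmads6, 12 in Osmads32 and 3 in wild type, and more low loci leave more room for a long stretch. The stretch was not silent in rep1: LOC_Os10g05930 stood at 5.57 FPKM there (3.83 and 7.32). Its cause was not tested.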
